A study of Mus musculus with 13 samples.

How the data were processed

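RNA of mouse bone marrow-derived macrophages was measured on 13 one-colour Agilent whole-genome arrays. The groups were control vehicle (n = 4), HDAC3 knockout (KO) vehicle (n = 3), control IL-4 (n = 3) and HDAC3 KO IL-4 (n = 3), with group and array number taken from the sample titles. Per the labels' protocols, RNA was amplified and labelled with a NuGEN kit and Cy3. The labels do not say whether arrays of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

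Per the file headers, the deposited scanner files hold spot intensity values on a linear scale from 1 channel, extracted with Agilent Feature Extraction 10.5.1.1. The submitters' processing notes name version 9.53 of that software, and limma without a version. The files' probe coordinates use the mm9 build. gProcessedSignal is the background-corrected intensity per the file headers. The deposited value table holds 39280 rows of linear intensity values whose column medians were 181 or 181.5 and whose 75th percentile was 772 in every column. Its correlation with log2 gProcessedSignal was at least 0.998 on every array. It leaves out 4099 non-control spots and holds 94 missing values. These columns resemble quantile normalized intensity, but the authors' steps are not given in the sources used here.

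Control spots and outlier-flagged spots were left out and spots of one probe were averaged. Of 41174 non-control probes, 101 were left out because every spot was an outlier on at least 1 array. No spot was saturated. Values are log2(gProcessedSignal) minus the array's 75th percentile. Probes well above background on every array of at least 1 group were kept (29055 probes), with the brightest probe per gene, which gave 20890 genes. Genes were named through RefSeq accessions in the reference table (25089 probes by systematic accession), and 76.5% of probes carry a symbol of that table. Others keep the file's name.

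Array precision is limited by the number of arrays and by signal over background. The share of non-control spots well above background ran from 56.2% to 83.2%. The lowest share was on control vehicle array 4, where negative controls averaged 131.3 against 56.25 to 81.83 on the others. Correlation between arrays of one group, across genes, ran from 0.980 to 0.993. The median SD over genes was 0.245 in KO IL-4, 0.186 in control IL-4, 0.181 in control vehicle and 0.149 in KO vehicle arrays. A fit of all groups shares 1 spread per gene, which may be too small for comparisons that use KO IL-4.

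Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 13 arrays in one fit), with Benjamini-Hochberg adjustment over genes and calls at an adjusted p under 0.05. The comparisons were HDAC3 loss in vehicle and under IL-4, IL-4 in control and in KO cells, and the interaction. A group in which a probe was not well above background on any array has a bound, given as "at least N-fold": the bright group's mean against the dim group's mean of, per array, the higher of the lowest well-above-background signal and the probe's own value. The 23 gene lists were tested with camera (preset correlation 0.01, adjusted over lists within a comparison), with an estimated correlation and fry beside it. The size of the IL-4 response was tested by exact permutation of genotype labels within treatment, and again on the residuals of an additive model of treatment and genotype. The lists, the tests of the comparisons and the alternatives were fixed before the data were examined, apart from an added alternative that leaves out the 2 arrays with the lowest share of spots well above background, and the permutation of residuals. The closing section names the tests of explanations that were chosen later.

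Named genes follow a rule fixed in advance. It takes the 10 largest changes each way for HDAC3 loss in vehicle and IL-4 in controls and the 6 largest each way elsewhere, among called genes whose groups do not overlap (not asked of the interaction) and whose name is not a placeholder. It adds up to 4 members per list by smallest adjusted p, Hdac3, Lyz2, Lyz1 and 9 macrophage activation genes. Some genes this rule takes are not reported here.

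Alternatives were quantile normalization, normexp (offset 50) with quantile normalization, median scaling, the authors' values, other probe filters and probe rules, trend and robust variance, slide as a fixed or random block, only the compared groups, array weights, a minimum log2 change of 1, leaving out each array, and splitting the control vehicle arrays. The 4 slides hold up to 4 arrays each, and every group lay at 1 array position of its own, so position and group cannot be told apart. Within a slide a group has 1 array at most, so no calls can be counted there. Scripts were tested on simulated data for 20890 genes. For HDAC3 loss in vehicle, 66% of genes planted at a log2 change of 1 and 96% at 2 were recovered, and for the interaction 32% and 86%. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for preparation and plots.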

Results

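Gene expression was compared in macrophages grown from the bone marrow of C57BL/6 mice. HDAC3 is a histone deacetylase that acts in corepressor complexes. Control cells carried floxed Hdac3 (exons 4 to 7 between loxP sites) without Cre, and KO cells carried the floxed gene and Cre driven by the lysozyme M promoter, so genotype and Cre go together. Cells received vehicle (0.1% bovine serum albumin) or 10 ng/mL IL-4, a cytokine that induces alternative activation, for 24 hours. The design asks what HDAC3 loss does at rest and under IL-4, and whether it alters the IL-4 response. Array numbers limit the precision: n = 4 for control vehicle and n = 3 for each other group.

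Hdac3 signal was lower in KO cells. Its log2 level was -2.01 ± 0.214 (SD, n = 4) in control vehicle and -3.41 ± 0.278 (SD, n = 3) in KO vehicle arrays, leaving 37.7% of the signal (limma adjusted p = 0.00295). Under IL-4, 34.9% was left (adjusted p = 0.00398, limma), with the probe well above background on 2 of 3 KO IL-4 arrays. The probe lies at chromosome 18, 38096625 to 38096647 (mm9). Its place relative to the deleted exons was not determined, and a probe outside them would not check the deletion. Lyz2, whose locus carries Cre, did not differ detectably between genotypes in vehicle (log2 fold change -0.02, SE 0.0837, adjusted p = 0.996). Under IL-4, Lyz2 was higher on every KO array (7.51 to 7.58) than on every control array (7.19 to 7.29). So was Lyz1 (5.68 to 6.04 against 5.03 to 5.11). In that comparison the groups did not overlap for 17.8% of all genes.

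**Figure D1:**
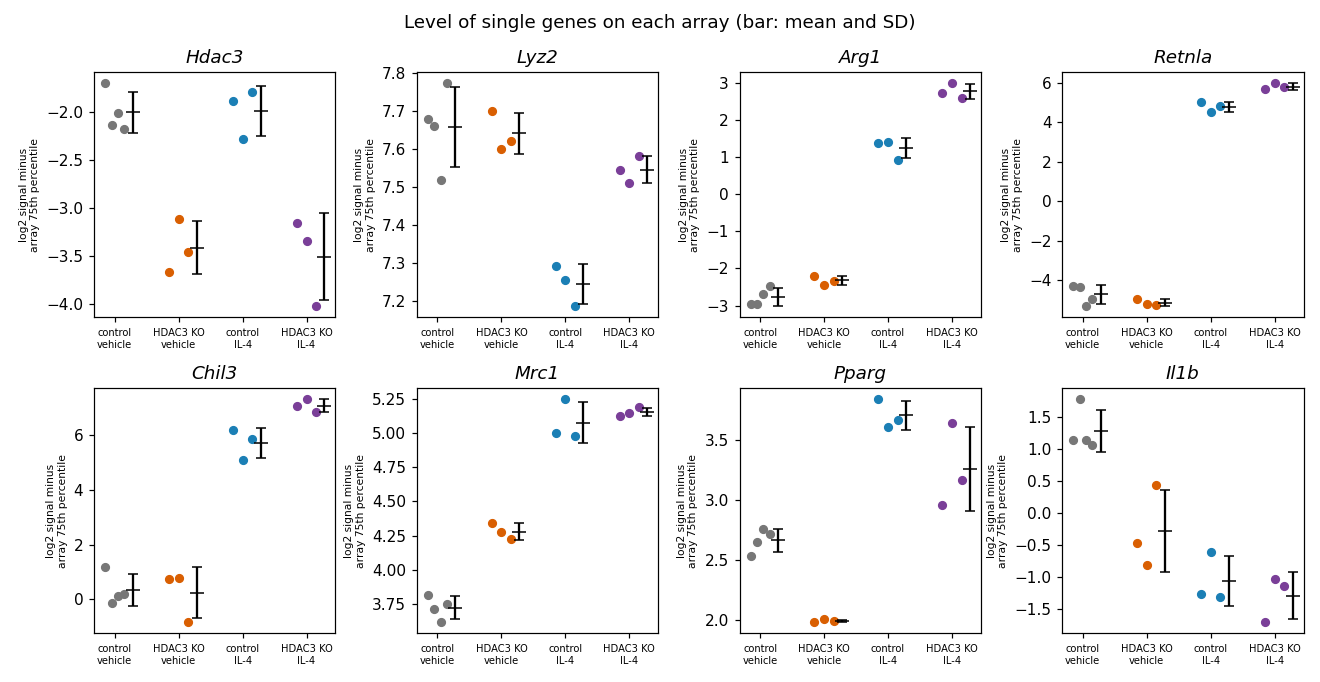
Level of 8 genes on each array, as log2 signal minus the array's 75th percentile, by group. Points are arrays and bars are the mean and SD. Hdac3 is lower on every KO array than on every control array, and Arg1, Retnla and Chil3 are higher on all IL-4 arrays than on all vehicle arrays.

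HDAC3 loss in vehicle changed genes in both directions. Siglecf, a sialic acid-binding receptor, had the largest rise among genes with a measured fold (log2 fold change 5.36, SE 0.363). Mmp13 rose by 3.88 and Mmp12 by 2.80, both matrix metalloproteinases. The chemokine genes Ccl2 and Ccl7 rose by 3.42 and 3.19, and the chemokine receptor Ccr1 by 3.70. Il1rl2, a receptor of interleukin-36 cytokines, was at least 11-fold higher, as it was not well above background on control arrays. Ptgs1 (cyclooxygenase-1) rose by 3.41, Tmem154 by 2.76 and Galnt9 by 3.20. Among genes that fell were Fgl2 (-3.59), Ly6a (-3.07), Ly6c2 (-2.84), Ly6f (-2.53), H2-Q8 (-2.85), H2-Ab1 (-2.54), Ms4a4c (-2.82), Ms4a4d (-2.49), Cd300e (-2.73) and the chemokine gene Ccl5 (-2.51). Ly6 and H2-Q family members are similar in sequence, so which member these probes report is uncertain, and another Ms4a4d probe went the other way. Adjusted p-values (limma) of these genes ran from 1.69e-06 for Ptgs1 to 0.00849 for Cd300e, whose adjusted p was 0.0537 without KO vehicle array 5 and 0.0539 without array 6. In all, 506 genes were higher and 470 lower of 20890 (limma), with 145 and 136 changed at least 2-fold. The groups did not overlap for 16.9% of genes, against 5.71% by chance. After blocking on slide the counts were 393 and 351. Leaving out 1 array moved a count by over 1.5 times for KO vehicle 5 (239 higher, 207 lower), KO vehicle 6 (239 and 209) and control vehicle 1, 3 and 4 (308, 293 and 294 lower). Median scaling gave 230 and 295, and array weights gave 971 and 829.

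By list, 27 of 34 interferon-stimulated genes fell and none rose (31 adjusted over the list alone; camera adjusted p = 7.02e-43, adjusted p = 0.0432 with an estimated correlation). Ifit3 fell by 1.82, Ifi44 by 1.64, Oasl1 by 1.53 and Xaf1 by 1.22 on the log2 scale. The list median was -0.787, and -0.917, -0.842 and -0.622 within slides 1 to 3. Of 23 sterol synthesis genes, 10 rose and none fell (15 adjusted over the list alone; adjusted p = 9.09e-12, adjusted p = 0.0432 with an estimated correlation), with Fdft1 at 0.61. The median was 0.380, and 0.5, 0.538 and 0.270 within slides. Hmgcs1 rose by 0.59, but another of its probes went the other way, and its mean over probes did not pass. Of 16 LXR target genes 5 rose (7 rose and 1 fell adjusted over the list alone), including the apolipoprotein genes Apoc1 (2.36) and Apoc2 (2.17). The adjusted p was 1.39e-06, and adjusted p = 0.144 with an estimated correlation. Of 27 matrix remodelling genes 8 rose (13 adjusted over the list alone), with Plaur, the urokinase receptor, at 2.51 and Spp1, osteopontin, at 1.1. The adjusted p was 9.40e-08, and adjusted p = 0.0701 with an estimated correlation. Within slides the medians were 0.204, 0.428 and 0.141 for LXR target genes and 0.339, 0.617 and 0.324 for matrix remodelling genes.

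Of 9 MHC class II genes 4 fell (4 fell and 2 rose adjusted over the list alone), which were H2-Ab1, Cd74 (-2.25), H2-Eb1 (-1.78) and H2-Aa (-1.77), with adjusted p = 0.00223, and adjusted p = 0.176 with an estimated correlation. These genes encode chains of the molecules that present antigen to T cells and the invariant chain. Of 31 alternative activation genes 11 rose and 4 fell (12 and 5 adjusted over the list alone; adjusted p = 0.000457, adjusted p = 0.144 with an estimated correlation). Egr2 (1.97), Clec7a (1.38) and Mrc1, the mannose receptor (0.56), rose, while Pparg, a lipid-activated nuclear receptor, fell by 0.67 on the log2 scale. The Pparg call was lost with slide as a block (adjusted p = 0.0611) and without any of 5 arrays, which were control vehicle 3 and 4 (0.0581 and 0.0558) and KO vehicle 5, 6 and 7 (0.0866, 0.0790 and 0.0588). Arg1 (0.45, adjusted p = 0.201), Chil3 (-0.10, adjusted p = 0.996) and Clec10a (-0.34, adjusted p = 0.471) did not pass. Of 40 lysosome and phagocytosis genes 12 rose and 2 fell (13 and 2 adjusted over the list alone; adjusted p = 0.000457, adjusted p = 0.336 with an estimated correlation), with the protease gene Ctsl at 1.52 and the receptor gene Axl at -1.10. Within slides the medians were -0.255, -0.877 and -0.313 for MHC class II, 0.262, 0.364 and 0.138 for alternative activation and 0.135, 0.15 and 0.121 for lysosome genes. With slide as a block the adjusted p was 0.0103 for MHC class II, 8.02e-38 for interferon-stimulated, 4.71e-11 for sterol synthesis, 9.82e-07 for LXR target and 4.74e-07 for matrix remodelling genes, and 0.00130 for the other lists.

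IL-4 in control cells raised the alternative activation genes. Retnla, a secreted marker of alternative activation, rose by 9.48 (SE 0.231; well above background on 1 of 4 control vehicle arrays), Chil3, a chitinase-like protein gene, by 5.37 and Arg1, which encodes arginase, by 4.02 on the log2 scale. The ribonuclease genes Rnase2a (6.32), Ear1 (4.75) and Ear10 (4.60) rose, and Ear3 was at least 15.4-fold and Cish, a feedback inhibitor of cytokine signalling, at least 11.1-fold higher. Probes of the Ear family cannot be assigned with certainty to one member. Cldn11 rose by 4.53, Ptgs1 by 4.40, Slc7a2, an arginine transporter, by 4.35 and Clec10a by 2.52, and Ppp1r3c was at least 4.77-fold higher. Formyl peptide receptor genes Fpr2 (-3.41) and Fpr1 (-2.94), the paired receptors Pilrb2 (-3.21) and Pilrb1 (-2.84), Slc13a3 (-3.32), Nfkbiz (-3.08), Cd300e (-2.95), Cxcl10 (-2.67), Adgre4 (-2.65), Fcrl1 (-2.58) and Il1b (-2.34) fell. In all, 576 genes were higher and 601 lower, with 220 and 132 changed at least 2-fold. After blocking on slide the counts were 443 and 438. The groups did not overlap for 16.7% of genes, against 5.71% by chance. Without control IL-4 array 12 the counts were 372 and 379, with median scaling 383 and 322, and with array weights 1318 and 1323. Adjusted p-values (limma) of the genes named above ran from 1.90e-09 for Retnla to 0.0052 for Cxcl10.

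Of 31 alternative activation genes 26 rose under IL-4 in controls and none fell (27 adjusted over the list alone), with a median of 2.48 (2.41, 2.45 and 2.38 within slides 1, 2 and 4). The adjusted p was 2.66e-55, and adjusted p = 0.000108 with an estimated correlation. Of 23 classical inflammatory genes 7 fell (8 fell and 3 rose adjusted over the list alone; adjusted p = 6.91e-05, adjusted p = 0.0146 with an estimated correlation), with the chemokine genes Ccl3 at -1.67 and Ccl4 at -1.40. Of 34 interferon-stimulated genes 11 fell (23 adjusted over the list alone; adjusted p = 4.90e-18, adjusted p = 0.137 with an estimated correlation), with Isg20 at -1.65 and Ifit3 at -1.58. Of 21 macrophage identity genes 9 fell and 2 rose (11 and 6 adjusted over the list alone; adjusted p = 0.000704, adjusted p = 0.137 with an estimated correlation), with the lipopolysaccharide coreceptor gene Cd14 at -2.16 and Tlr2 at -1.41. Within slides 1, 2 and 4 the medians were -0.459, -0.404 and -0.287 for inflammatory, -0.531, -0.397 and -0.385 for interferon-stimulated and -0.271, -0.223 and -0.451 for macrophage identity genes. With slide as a block the adjusted p was 3.95e-49 for alternative activation, 0.000244 for inflammatory, 1.16e-16 for interferon-stimulated and 0.000852 for macrophage identity genes.

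In KO cells IL-4 raised the same markers. Retnla was at least 995-fold higher, Chil3 rose by 6.83, Arg1 by 5.09 (SE 0.174), Irf4, a transcription factor of alternative activation, by 2.98 and Clec10a by 2.15 on the log2 scale. Ear10 (5.82) and Rnase2a (5.81) rose, and Ear3 was at least 33.8-fold higher. Slc13a3 (-2.58), Ifit3 (-2.33), Fpr2 (-2.30) and Fpr1 (-2.26) fell, and Slc24a3 was at least 3.22-fold lower. In all, 241 genes were higher and 212 lower, with 112 and 65 changed at least 2-fold. Of 31 alternative activation genes 24 rose (29 adjusted over the list alone; adjusted p = 6.49e-64, adjusted p = 5.85e-05 with an estimated correlation), with medians of 1.42, 1.87 and 1.61 within slides 1 to 3. Of 34 interferon-stimulated genes 15 fell (26 adjusted over the list alone; adjusted p = 3.65e-25, adjusted p = 0.0805 with an estimated correlation), with medians of -0.312, -0.576 and -0.885 within slides. Of 23 classical inflammatory genes 5 fell (8 fell and 1 rose adjusted over the list alone; adjusted p = 0.000903, adjusted p = 0.0432 with an estimated correlation), with medians of -0.297, -0.272 and -0.428. Of 9 MHC class II genes 2 rose (5 adjusted over the list alone; adjusted p = 3.06e-05, adjusted p = 0.107 with an estimated correlation), with medians of 0.265, 1.22 and 0.426. In controls 1 of these rose, H2-DMa by 0.72 (2 adjusted over the list alone; adjusted p = 0.00647, adjusted p = 0.308 with an estimated correlation, adjusted p = 0.00467 with slide as a block), with medians of 0.471, 0.716 and 0.723 within slides 1, 2 and 4, a call lost without control IL-4 12 (0.0560). Cd74 rose by 1.91 in KO cells. There H2-Ab1 was higher by 1.47 (adjusted p = 0.0242), but another of its probes went the other way and the call was lost with slide as a block (0.0640) and without KO vehicle 5, 6 or 7 (0.0964, 0.0804 and 0.0921) or KO IL-4 14 (0.105). After blocking on slide the adjusted p was 4.88e-57 for alternative activation, 5.84e-22 for interferon-stimulated, 0.00187 for inflammatory and 8.90e-05 for MHC class II genes. Stress and RNA quality genes shifted too in KO cells, where 1 of 17 rose, Ier3 by 1.25 (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.000105, adjusted p = 0.441 with an estimated correlation, adjusted p = 0.000227 with slide as a block), with medians of 0.212, 0.390 and 0.156 within slides. In controls 5 of these rose, among them Ier3 (2.15), and 2 fell, among them Fos (-0.89), and the list did not pass (adjusted p = 0.0515).

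With slide as a block, IL-4 in KO cells raised 194 and lowered 170 genes. The groups did not overlap for 18.2% of genes, against 10% by chance. A count moved by over 1.5 times without KO vehicle 5 (156 and 139), 6 (127 lower) or 7 (145 and 104), or KO IL-4 15 (133 lower), with the compared groups alone (83 and 31), with trend and robust variance (419 and 351), with median scaling (106 lower) and under normexp (414 and 400).

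Under IL-4, HDAC3 loss again raised Siglecf (4.88), Mmp13 (3.79), Il1rl2 (3.54), Ccl2 (3.25), Ccr1 (2.92) and Plaur (2.69), and lowered Ly6a (-3.88), Ly6c2 (-3.39), Ly6f (-3.01), Cldn11 (-2.84), Ms4a4d (-2.84) and Ifit3 (-2.57). Arg1 was higher by 1.53 (SE 0.174, limma adjusted p = 0.000694). Retnla was higher by 1.02 (adjusted p = 0.0439), a call lost with slide as a block (0.0600), with median scaling (0.0582), and without any of 10 arrays. These were control vehicle 4 (0.0565), KO vehicle 5 to 7 (0.0641, 0.0699, 0.0634), control IL-4 9, 10 and 12 (0.0651, 0.165, 0.126) and KO IL-4 13 to 15 (0.0682, 0.153, 0.105). Of 31 alternative activation genes 6 rose and 4 fell (11 and 7 adjusted over the list alone; adjusted p = 0.0212, adjusted p = 0.426 with an estimated correlation, adjusted p = 0.00658 with slide as a block), with medians of 0.123 and 0.490 within slides 1 and 2, a call lost without KO IL-4 14 (0.303). Chil3 (1.36, adjusted p = 0.160), Mrc1 (0.08, adjusted p = 0.780) and Clec10a (-0.71, adjusted p = 0.0698) did not pass. In all, 424 genes were higher and 334 lower, with 121 and 118 changed at least 2-fold. Of 34 interferon-stimulated genes 27 fell (29 adjusted over the list alone; adjusted p = 3.44e-39, adjusted p = 0.0329 with an estimated correlation), with medians of -0.657 and -1.07 within slides 1 and 2. Of 23 sterol synthesis genes 11 rose (15 adjusted over the list alone; adjusted p = 2.13e-13, adjusted p = 0.0329 with an estimated correlation), with medians of 0.354 and 0.508. Of 27 matrix remodelling genes 7 rose (13 rose and 1 fell adjusted over the list alone; adjusted p = 3.86e-09, adjusted p = 0.0453 with an estimated correlation), with medians of 0.294 and 0.676. Of 16 LXR target genes 6 rose (11 rose and 2 fell adjusted over the list alone; adjusted p = 3.58e-09, adjusted p = 0.109 with an estimated correlation), with medians of 0.387 and 1.01. After blocking on slide the adjusted p was 2.76e-31, 4.04e-12, 1.17e-08 and 6.65e-09 for these lists in turn.

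With slide as a block, HDAC3 loss under IL-4 raised 301 and lowered 274 genes. The groups did not overlap for 17.8% of genes, against 10% by chance. A count moved by over 1.5 times without control IL-4 10 (242 higher) or 12 (250 and 191) or KO IL-4 14 (265 higher), with the compared groups alone (49 and 40), with median scaling (216 and 204), with array weights (700 and 703) and under normexp (510 lower).

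**Figure D2:**
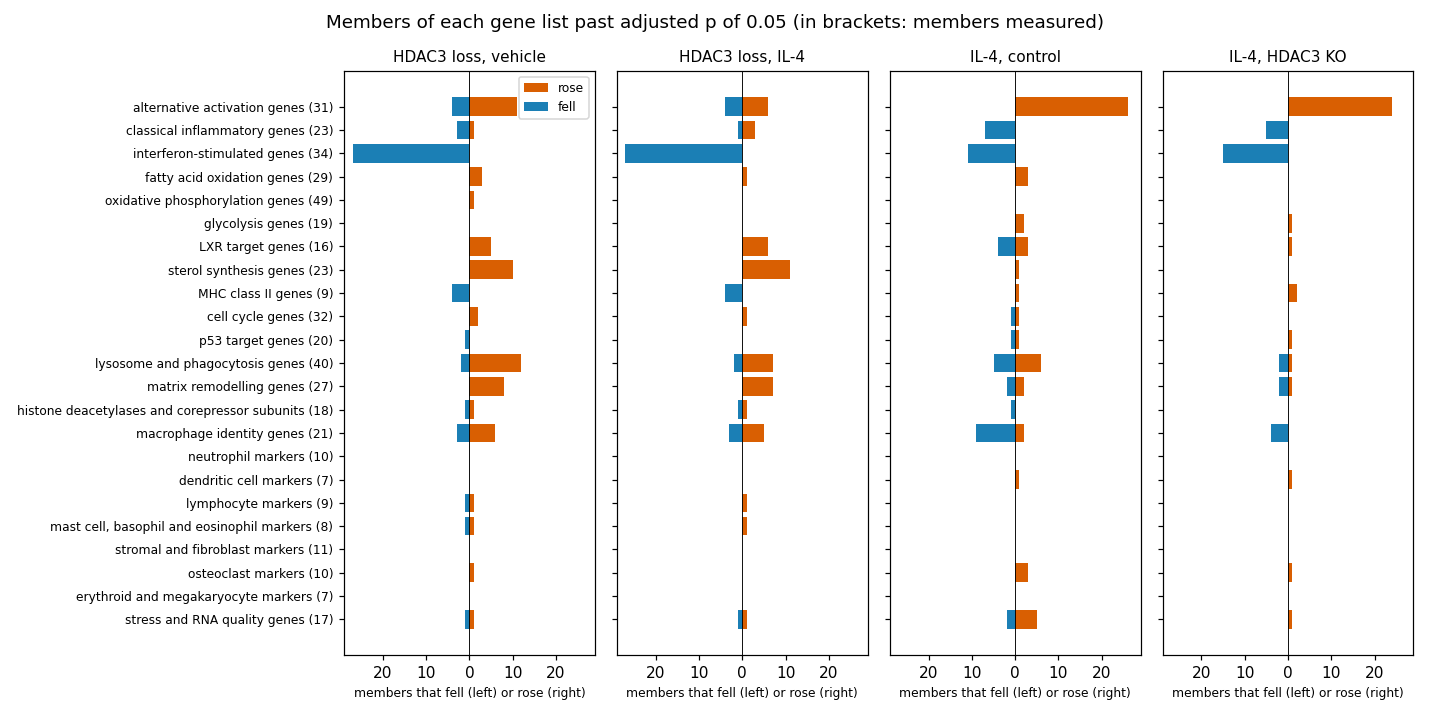
Members of each of 23 gene lists that rose (right) or fell (left) past an adjusted p of 0.05, in 4 comparisons, with the number measured in brackets. Interferon-stimulated genes fell in 27 of 34 cases after HDAC3 loss in vehicle, and 26 of 31 alternative activation genes rose under IL-4 in controls.

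The interaction called 1 gene. Ptgs1 rose by 4.40 under IL-4 in controls. Its log2 level went from 1.15 ± 0.0923 (SD, n = 3) in KO vehicle to 2.69 ± 0.299 (SD, n = 3) in KO IL-4 arrays. The difference of responses was -2.86 (SE 0.230, limma adjusted p = 0.00116). HDAC3 loss had already raised Ptgs1 by 3.41 in vehicle, so the smaller rise in KO cells began from a higher level. At an unadjusted p under 0.05 there were 811 of 20890 genes. That is fewer than chance alone would give at this threshold, so the count is no sign of further differences. Arg1 (1.08, adjusted p = 0.677), Clec7a (-1.04, adjusted p = 0.197) and Mrc1 (-0.48, adjusted p = 0.865) did not pass, and for Retnla no difference of responses is given, as it was not well above background on any KO vehicle array. The counts were 2 higher and 5 lower under normexp, 4 and 6 with trend and robust variance, and 1 and 3 without KO vehicle 7. Without KO vehicle 6, 1 gene was higher, and with slide as a block 0 were higher and 1 lower. Among 897 genes induced over both genotypes the median interaction was -0.130 on the log2 scale, with the larger response in KO cells for 32.9% (exact permutation p = 0.279, two-sided, 700 relabelings). Among 839 repressed genes it was 0.129, with the larger response in KO cells for 28.8% (exact permutation p = 0.200). Some of these relabelings turn the interaction into the genotype effect, which widens their spread. With the genotype effect common to both treatments removed first, an approximate test chosen after these p-values were seen, the permutation p was 0.217 for induced and 0.00429 for repressed genes, the latter 0.0629 without KO IL-4 13. The induced median was -0.0375, -0.0712 and -0.202 without KO IL-4 13, KO IL-4 15 and KO vehicle 7, and -0.195 without KO IL-4 14 (exact permutation p = 0.0486). The repressed median was 0.0741 without KO IL-4 13. After blocking on slide the medians were -0.146 and 0.124.

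HDAC3 loss in vehicle and IL-4 in controls shifted many genes alike. Both called 147 genes higher and 165 lower, against 13.9 and 13.5 for independent lists, and 53 went opposite ways, against 27.5. Ptgs1, Clec7a and Ifit3 went the same way in both. After HDAC3 loss 11 of 31 alternative activation genes rose and 4 fell, and these 4 rose under IL-4. The log2 fold changes were -0.68 and 2.54 for Irf4, -0.73 and 2.54 for Socs1, -0.94 and 2.49 for Ccl8. For Pparg they were -0.67 and 1.05, the fall being lost in the settings given above. These 4 are named here for their opposite directions, not by the rule. Cdc6, a replication factor gene, was higher by 0.95 after HDAC3 loss and lower under IL-4 (-0.75), the latter call being lost under normexp and with median scaling. The correlation of log2 fold changes across genes was 0.377. Simulated arrays without group differences, controls included, gave a mean of 0.427, as both effects share 1 control group. The covariance was 0.0481, against 0.0236 simulated, a difference of 0.0245. With the control arrays split so that the effects shared none, the covariance averaged 0.0206 (0.00752 to 0.0333) and 120 to 136 genes were called the same way. Spearman's rho across all genes was 0.350, and from -0.0630 to 0.162 over these splits, below 0.1 in 5 of 6. With slide as a block the correlation was 0.344, the covariance 0.0427, and 216 genes were called the same way and 31 opposite ways. Without 1 array, the same-way count fell to 177 for KO vehicle 5 and 6, 193, 192 and 206 for control vehicle 2, 3 and 4, and 200 for control IL-4 12. The opposite count fell to 25, 31, 27 and 25 for control vehicle 1 to 4, 17, 16 and 31 for KO vehicle 5 to 7, and 33, 34 and 26 for control IL-4 9, 10 and 12. Genes are not independent replicates.

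**Figure D3:**
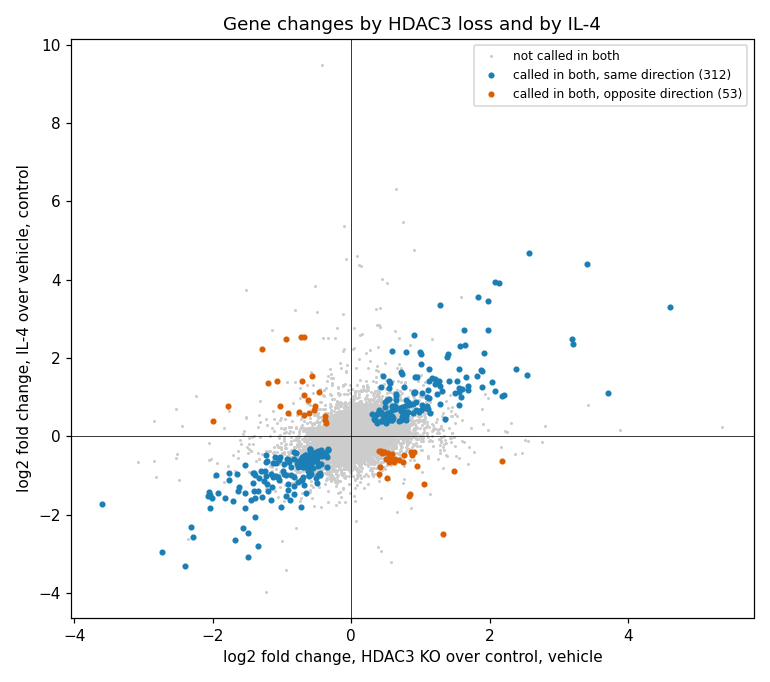
Log2 fold change of each gene by HDAC3 loss in vehicle (x axis) and by IL-4 in control cells (y axis). Of the genes called in both, 312 went the same way and 53 opposite ways. Both effects use the same control vehicle arrays.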

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

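The tests on shared control arrays, on dendritic cell and lymphocyte markers, on eosinophil, basophil and mast cell markers and on relabelings with the genotype effect removed were chosen after their results were seen. Ptgs1 had a different IL-4 response by genotype (-2.86 on the log2 scale). So did 3 lists by camera: alternative activation genes (median -0.343, adjusted p = 0.0109), interferon-stimulated genes (-0.145, adjusted p = 0.0109) and macrophage identity genes (0.237, adjusted p = 0.000317). None held with an estimated correlation (adjusted p = 0.646, 0.952 and 0.202). With slide as a block the adjusted p-values were 0.0857, 0.0475 and 0.00160. Within slides 1 and 2, the only ones that hold every group, the medians were -0.404 and 0.0539 for alternative activation, 0.223 and -0.241 for interferon-stimulated and 0.00758 and 0.227 for macrophage identity genes, so the direction of the first pair of lists turns between slides. The alternative activation call was also lost without control vehicle 2 (0.0553), control IL-4 9 or 12 (0.0771, 0.0507) or KO IL-4 13 (0.316), and the interferon call without KO vehicle 7 (0.696), control IL-4 10 or 12 (0.196, 0.0913) or KO IL-4 15 (0.136).

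Among control vehicle arrays, 1 array lay far from the other 3 for 12 of the values tested (7 array measures, 244 genes, 23 lists), where chance gives about 1 in 20. The gap over the range was 0.832 for the negative controls of array 4, 0.875 for Scd2, 0.888 for Il1b, 0.997 for Ier3, 0.955 for Cd83, 0.848 for Pgk1, 0.865 for Epx, 0.850 for Prss34, 0.837 for Zmat3, 0.831 for Mylip, and 0.836 and 0.912 for the mean of fatty acid oxidation and of lysosome and phagocytosis genes.

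HDAC3 loss and IL-4 shifted many genes the same way. With the controls split so that the effects shared no array, at least 120 genes were called the same way, against at most 8.17 for independent lists, which argues against shared control errors as the whole cause. The split effects still share slides, whose arrays share some variation, and no split was run with slide as a block. Independent lists are thus a rough reference, and variation shared by slide stays open. Removing the trend on mean level left a mean split covariance of 0.0231 (before: 0.0206), which argues against the dimmer control vehicle arrays. Under other scalings it was at least 0.0176, though median scaling cannot move a covariance. Each group held 1 array position, so position and group cannot be told apart, and a shared biological response stays open and untested.

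Interferon-stimulated genes were lower after HDAC3 loss. The median nearest 0 under 4 scalings was -0.787, which argues against scaling. Of the 27 that fell, 1 lies within 20 Mb of Lyz2 or Hdac3, which argues against linked chromosome segments that change only their own genes. The count cannot test whether a gene in such a segment acts on list members elsewhere, so that stays open. Dendritic cell markers had a median of -0.0216 (SD 0.357 over 7 genes) and lymphocyte markers 0.111 (SD 0.806 over 9), but members went both ways, and 4 of 9 MHC class II genes fell (adjusted p = 0.00223, adjusted p = 0.176 with an estimated correlation), so fewer such cells stay open. Array position, Cre itself and HDAC3 loss stay open too.

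Siglecf was far higher after HDAC3 loss. Its log2 fold change was at least 4.61 under 4 scalings (5.36 with the 75th percentile). The 7 other markers of eosinophils, basophils and mast cells had a median of 0.122 (SD 0.462). Of these, Ccr3 fell (-0.913, limma adjusted p = 0.000698) and 6 did not pass. However, 5 of the 7 were not well above background on every vehicle array. Ccr3 has a high level in controls that would hide a small share of such cells, so these cells stay open. The labels describe no sort that would remove them. Array position, Cre and HDAC3 loss stay open too.

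Other splits of the arrays called far fewer genes for HDAC3 loss in vehicle (976 genes, highest other 2, 1 of 35 splits as large) and IL-4 in controls (1177, highest other 14, 1 of 35). These splits move arrays across slides, although arrays of a slide share some variation. Exchanges within the 3 shared slides are too few for a share under 0.05, so chance is excluded only if slides are set aside. As arrays of a group may be technical repeats, the splits cannot exclude chance differences between cultures or animals. For IL-4 in KO cells (453, highest other 0) and HDAC3 loss under IL-4 (758, highest other 1), 10 splits are too few for a share under 0.05. For the interaction, 6 of 100 labelings, the real one included, called at least 1 gene, and this count does not exclude chance. The highest called 654. It and another with 578 exchanged the genotypes in vehicle only, which turns the contrast into the genotype effect and so points to that structure of the samples. With the genotype effect common to both treatments removed, 3 of the 100 called at least 1 gene (highest other 1), an approximate count, so whether chance gave the call is not settled.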

How the results depend on the processing

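No call of a named gene changed sign under 4 scalings, and the fixed slide block kept each comparison's gene counts within 1.5 times. The causes were not tested, and signal over background limits dim genes. Scan date was not run because it gives no grouping apart from slides, and camera takes no random block. Leaving out the 2 arrays with the fewest spots well above background was chosen after seeing the data. Arrays of different groups on a slide correlated with a median of 0.270 in their deviations from group means, against -0.0872 across slides, so arrays of a slide share some variation, though only 12 of 16 pairs were over 0.1. The slide block left 31 genes opposite in HDAC3 loss and IL-4, and ended list calls for p53 (0.067 for HDAC3 loss in vehicle, 0.111 for IL-4 in controls), lysosome genes (0.118, IL-4 in controls), MHC class II genes (0.0837, HDAC3 loss under IL-4) and alternative activation genes (0.0857, interaction). For IL-4 in controls, the p53 and lysosome lists each had a camera adjusted p of 0.0412, and 0.700 with an estimated correlation. These calls were also lost without any of 4 arrays for p53 and any of 3 for lysosome genes. The p53 list was called for IL-4 in KO cells too, a call lost without KO vehicle 7 (0.0584) or KO IL-4 13 (0.0898).

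Hmgcs1 reversed under IL-4 in controls with the mean over probes (-0.0303). Within slide 1, fatty acid oxidation (-0.0475) and lysosome genes (-0.0727) reversed for HDAC3 loss under IL-4, as did interferon-stimulated genes for the interaction (0.223), and within slide 2 alternative activation genes for the interaction (0.0539).

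Counts are higher then lower. For HDAC3 loss in vehicle they were 230 and 295 with median scaling, 971 and 829 with array weights, 145 and 136 with a minimum log2 change of 1, and 323 and 275 without the 2 arrays with the fewest spots well above background. For IL-4 in controls they were 383 and 322, 1318 and 1323, 220 and 132, and, without the 2 arrays, 391 lower. For IL-4 in KO cells they were 414 and 400 under normexp, 419 and 351 with trend and robust variance, 83 and 31 with the compared groups alone, 112 and 65 with the minimum change, 156 and 105 without the 2 arrays, and 106 lower with median scaling. For HDAC3 loss under IL-4 they were 216 and 204 with median scaling, 49 and 40 with the compared groups alone, 700 and 703 with array weights, 121 and 118 with the minimum change, 268 and 171 without the 2 arrays, and 510 lower under normexp. For the interaction they were 2 and 5 under normexp, 4 and 6 with trend and robust variance and 1 and 3 with array weights, and 2 lower with quantile normalization, the authors' values or probes well above background on all arrays.

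For the similarity of HDAC3 loss and IL-4, normexp gave a covariance of 0.0252 with 506 genes the same way and 83 opposite, median scaling 171 and 14, and omission of the 2 arrays 169 and 20. No filter gave a correlation of 0.433, a covariance of 0.0664 and 24 opposite, and the filter on all arrays a covariance of 0.0397. Over the 6 control splits the correlation was 0.107, 0.158, 0.0445, 0.234, 0.173 and 0.102, the covariance 0.0167, 0.0236, 0.00752, 0.0333, 0.0260 and 0.0164, the same-way count 126, 120, 124, 123, 136 and 127 and the opposite count 12, 16, 11, 10, 8 and 9. With an estimated correlation 9 of 40 list calls held. By fry, 15 of the 40 were lost and 2 other list tests passed. After HDAC3 loss in vehicle, the fry adjusted p was 0.000127 for interferon-stimulated and sterol synthesis genes. It was 0.000202 for matrix remodelling and alternative activation genes, 0.00184 for LXR target and 0.00316 for MHC class II genes. Osteoclast (0.00223), lysosome (0.0131) and inflammatory genes (0.0171) passed too, but fatty acid oxidation (0.058) and p53 target genes (0.241) did not.

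Leaving out 1 array gave 239 to 584 higher and 207 to 513 lower genes for HDAC3 loss in vehicle, 372 to 683 and 379 to 699 for IL-4 in controls, 145 to 242 and 104 to 225 for IL-4 in KO cells, 242 to 385 and 191 to 333 for HDAC3 loss under IL-4, and 0 to 1 and 1 to 3 for the interaction. The correlation was 0.294 to 0.457, the covariance 0.0399 to 0.0664, the same-way count 177 to 358, the opposite count 16 to 59, the induced median -0.202 to -0.0375 (stronger without KO IL-4 14, -0.195), the repressed median 0.0741 to 0.166 and the list calls 35 to 44.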

Other observations

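Of 4 metabolic lists, oxidative phosphorylation and fatty acid oxidation passed by camera for IL-4 in control cells, with neither call held under an estimated correlation (adjusted p = 0.700 and 0.372), while glycolysis (adjusted p = 0.190) and sterol synthesis (adjusted p = 0.915) did not pass. Of 49 oxidative phosphorylation genes 0 passed singly in controls or in KO cells (0 adjusted over the list alone), with medians of 0.204 (adjusted p = 2.89e-07, adjusted p = 0.700 with an estimated correlation) and 0.184 (adjusted p = 1.17e-10, adjusted p = 0.441 with an estimated correlation). Of 29 fatty acid oxidation genes 3 rose in controls (12 adjusted over the list alone; adjusted p = 1.97e-06, adjusted p = 0.372 with an estimated correlation), among them Fabp4, a fatty acid-binding protein gene (1.1), and Hadhb, a subunit of the mitochondrial trifunctional protein (0.61). In KO cells 0 of the 29 rose (4 adjusted over the list alone; adjusted p = 3.41e-07, adjusted p = 0.364 with an estimated correlation), with medians of 0.154, 0.358 and 0.285 within slides 1 to 3. Blocked by slide, the adjusted p was 1.74e-05 and 1.88e-09 for oxidative phosphorylation and 2.74e-05 and 2.29e-06 for fatty acid oxidation. Within slides 1, 2 and 4 the medians in controls were 0.300, 0.151 and 0.157, and 0.254, 0.262 and 0.197.

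Further lists passed by camera after HDAC3 loss in vehicle, none of them with an estimated correlation. Of 29 fatty acid oxidation genes 3 rose (7 adjusted over the list alone; adjusted p = 0.00134, adjusted p = 0.516 with an estimated correlation), among them Fabp4 (1.49) and Fabp5 (1.37). Of 10 osteoclast markers 1 rose (1 adjusted over the list alone), the proton pump subunit gene Atp6v0d2 by 1.12, with a list median of 0.402 (adjusted p = 0.00834, adjusted p = 0.0969 with an estimated correlation). Of 23 classical inflammatory genes 1 rose, Ccl2, and 3 fell (1 and 7 adjusted over the list alone; adjusted p = 0.0203, adjusted p = 0.0969 with an estimated correlation), a call lost without control vehicle 1 (adjusted p = 0.0585). Of 20 p53 target genes 1 fell (1 adjusted over the list alone; adjusted p = 0.0272, adjusted p = 0.516 with an estimated correlation), a call lost with slide as a block (0.0670) and without control vehicle 1, 3 or 4 (0.0541, 0.0735, 0.0991) or KO vehicle 7 (0.224). Blocked by slide, the adjusted p was 0.00130 for fatty acid oxidation, 0.00592 for osteoclast and 0.0165 for inflammatory genes. Within slides 1 to 3 the medians were 0.125, 0.358 and 0.00186 for fatty acid oxidation, 0.376, 0.365 and 0.369 for osteoclast, -0.314, -0.184 and -0.0804 for inflammatory and -0.100, -0.00399 and -0.291 for p53 target genes.

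Of 21 macrophage identity genes 6 rose and 3 fell after HDAC3 loss in vehicle (7 and 5 adjusted over the list alone; adjusted p = 0.907), with the integrin gene Itgam at 1.44 and the chemokine receptor gene Ccr2 at -1.38, and a median (-0.017) and mean (0.0237) of opposite sign. The remaining lists did not pass by camera in that comparison, with adjusted p = 0.580 for oxidative phosphorylation, 0.782 for glycolysis and 0.125 for cell cycle genes. It was 0.782 for histone deacetylases and corepressor subunits and 0.907 for stress and RNA quality genes. By fry, cell cycle genes passed (adjusted p = 0.0171). For markers of other cells the adjusted p was 0.536 (neutrophils), 0.845 (dendritic cells), 0.782 (lymphocytes), 0.733 (mast cells, basophils and eosinophils), 0.560 (stromal cells) and 0.560 (erythroid cells and megakaryocytes).

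Under IL-4, 4 further lists passed by camera for HDAC3 loss, none of them with an estimated correlation. Of 21 macrophage identity genes 5 rose and 3 fell (9 and 3 adjusted over the list alone; adjusted p = 0.00129, adjusted p = 0.109 with an estimated correlation), with Itgam at 1.85. Of 40 lysosome and phagocytosis genes 7 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.000676, adjusted p = 0.426 with an estimated correlation). Of 29 fatty acid oxidation genes 1 rose, Fabp5 by 1.16 (1 adjusted over the list alone; adjusted p = 0.000676, adjusted p = 0.527 with an estimated correlation). Both of the latter calls were lost without KO IL-4 14 (0.118 for each). Of 9 MHC class II genes 4 fell (4 adjusted over the list alone; adjusted p = 0.0468, adjusted p = 0.428 with an estimated correlation), which were H2-Ab1 (-1.77), H2-Aa (-1.58), H2-Eb1 (-1.55) and Cd74 (-1.37), the last a call lost without any of 4 arrays (adjusted p from 0.0666 to 0.0927). The list call was lost with slide as a block (0.0837) and without any of 7 arrays (adjusted p from 0.0512 to 0.248). Blocked by slide, the adjusted p was 0.00449 for macrophage identity, 0.00199 for lysosome and 0.000627 for fatty acid oxidation genes. Within slides 1 and 2 the medians were 0.177 and 0.257 for macrophage identity, -0.0727 and 0.378 for lysosome, -0.0475 and 0.413 for fatty acid oxidation and -0.0283 and -0.649 for MHC class II genes.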
